A study of Mus musculus with 22 samples.

How the data were processed

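RNA was measured in 22 mouse samples in 7 groups. Megakaryocytes, the bone marrow cells that shed platelets, were sorted on CD41 and DNA content into an 8N gate and a gate of 16N and above, called 16N-plus here, and each gate was collected from Cre-negative controls and from Pf4Cre-Srsf3fl/fl mice, in which Cre driven by the platelet factor 4 promoter deletes floxed Srsf3 in the megakaryocyte lineage. Each of these 4 groups had 3 samples. Washed platelets came from wild type mice (3 samples), Cre-negative controls (3) and knockouts (4). Only the knockouts carry the Cre transgene, so in every genotype comparison an effect of the transgene cannot be told apart from loss of Srsf3. Per the labels' protocols, megakaryocyte libraries were stranded total RNA libraries sequenced on an Illumina instrument, and platelet libraries were amplicon panels made from 10 ng of RNA and sequenced on an Ion Proton. The 2 data types were therefore not compared by level. The labels do not say whether the samples of a group came from separate animals, so the authors' p-values per gene measure the spread between these samples. P-values of the list and overlap tests take genes as their units and do not measure replication between samples.

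The values used here are the authors' own comparisons, with no values per library. Per the submitters' processing notes, the tools named were Trimmomatic, STAR, Picard, Subread, featureCounts, edgeR and DESeq2 with the build mm10, without versions or roles. Per the file headers, the 5 megakaryocyte tables have the columns of the authors' edgeR quasi-likelihood output: a log2 fold change, a mean log2 CPM over libraries, an F score, a p-value and an adjusted p. They list the same 9326 genes, whose lowest mean log2 CPM was 4.23, so a filter on low expression preceded them. The platelet table has 23930 rows with the columns of the authors' DESeq2 output: a deposited signal (the mean count divided by size factors), a deposited log2 fold change with its standard error (SE), a test score, a p-value and an adjusted p. Adjusted p was listed for 12611 of its rows, and the lowest mean normalised count among these was 0.707. The deposited platelet fold changes appear moderated, since the SE levelled off at 1.58 in rows of very low signal. Depth per library is unknown.

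The deposited tables do not state which group is the numerator. The difference between the genotype tables equals the difference between the ploidy tables to rounding, which ties the sign of both contrasts, so that either all 5 megakaryocyte tables are knockout minus control and 16N-plus minus 8N, or all are reversed. The plan fixed before the data were examined was to read the direction from Srsf3. Srsf3 did not settle it: read as knockout minus control, its deposited log2 fold change was positive and not past the threshold, and a gene-level value need not follow the deleted exons. The direction used throughout was instead chosen after the values were seen, from the higher platelet genes and lower mitosis and DNA replication genes expected at higher ploidy. The directions of those lists in the control ploidy step are therefore not independent evidence. With the other orientation every megakaryocyte sign printed here would turn and the counts of higher and lower genes would swap, while total counts, sizes and two-sided p-values would stay. The platelet direction was chosen from its positive correlation with the megakaryocyte genotype tables, so the sign of that correlation is not independent evidence either. Under this choice the platelet signs would turn with the megakaryocyte signs. No other relation was used to set the platelet direction, so the platelet signs could also be reversed on their own. Which platelet controls entered the deposited comparison is not stated, so the 3 platelet comparisons planned could not be separated and 1 comparison of knockout with control is given.

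Fold changes compare levels relative to the rest of each library, so they do not give RNA amounts per cell. Genes were called at an adjusted p under 0.05 as the authors deposited it. For megakaryocytes an SE was computed as the size of the deposited log2 fold change over the square root of its F; it is unstable where F is near 0. Its median over genes with F above 0.5 was between 0.16 and 0.26 across the tables, and the SE of the table that combines ploidies was predicted from the tables of each ploidy with a median ratio of 0.99 over 1122 genes. The F and p pairs imply a denominator of 339.5 degrees of freedom, so spread was strongly pooled across genes from 12 libraries. The genotype by ploidy interaction was computed here, with a normal approximation and Benjamini-Hochberg adjustment. Its test score was the difference of the genotype log2 fold changes at the 2 ploidies over the root of their summed squared SEs. It is approximate and takes the 2 gates as independent. The sample titles do not say whether both gates came from the same mice. The 28 gene lists were fixed before the data were examined and tested with limma's cameraPR (limma 3.58.1, R 4.3.3) on the signed statistic with a preset correlation of 0.01 and adjustment over lists within a comparison. Members were matched by symbol, or by a unique synonym that is no other gene's official symbol. Overlaps of calls were tested with one-sided Fisher exact tests per direction, beside the number expected for independent lists. Symbols came from a gene name table that matched 9300 of the 9326 identifiers, and coordinates from GENCODE M21 on GRCm38, the assembly also called mm10; the annotation the authors used is not given in the sources used here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

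The named genes follow a rule fixed in advance: Srsf3; per direction the 8 called genes of smallest adjusted p; the 4 highest and 4 lowest fold changes among called genes with mean expression at or above the median; and up to 4 called members per list. The rule also allowed canonical members that did not pass; which of these to give (Pf4, Itga2b, Gp1ba, Gp9, Myh9 and Actb) was chosen after their values were seen, as was giving Pf4 and Gp9 in platelets, where they passed. Predicted models, pseudogenes and identifiers without a symbol were skipped. On simulated data with 200 changed genes among 9326, the interaction test recovered 98% of genes changed by a log2 size of 2 and 39% of those changed by a log2 size of 1, with 3.52% of its calls false, and called 0 genes when nothing was changed. The simulated noise was independent between genes and had exactly the SEs the test used. These rates therefore do not cover errors in the SEs or noise shared between genes. Intervals over genes came from 2000 bootstrap resamples, except 1000 for the slope of the knockout step on the control step. The common-fraction test used 300 simulations. Alternatives were a stricter adjusted p, a minimum fold change, genes at or above the median of mean expression, a recomputed adjustment, other list settings and, added after the data were seen, centring on the median gene and other SE estimates for the interaction. Refits, leaving out libraries and a replicate block need values per library and were not run.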

Results

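The data set asks what loss of the splicing factor SRSF3 does to megakaryocyte RNA during maturation and to the RNA that platelets carry. It holds 12 megakaryocyte libraries in 4 groups of genotype and ploidy, with 3 samples each, and 10 platelet libraries in 3 groups. Values are the authors' comparisons. Signs are given as knockout minus control and as 16N-plus minus 8N; this direction was inferred from the values and is not stated in the deposited tables.

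Srsf3 (ENSMUSG00000071172, chromosome 17, 29032628 to 29043373 on the plus strand, GRCm38), the deleted gene, was not called in any megakaryocyte comparison. In the inferred direction, the authors' deposited table listed Srsf3 at a log2 fold change of 0.33 in 8N cells (SE 0.21; the authors' edgeR adjusted p = 0.80), and at 0.43 in 16N-plus cells (SE 0.27; adjusted p = 0.56). The authors' deposited table that combines ploidies gave Srsf3 0.38 (SE 0.17; edgeR p = 0.028 unadjusted, adjusted p = 0.28). These values go against the sign a loss of transcript would give, and they check neither the deletion nor the direction, since a gene-level value covers exons outside the deleted part. Srsf3 has no row among the platelet rows used here.

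Relative to the rest of the library, control megakaryocytes of 16N-plus had more RNA of platelet genes and of the mitochondrial genome than 8N cells. They had relatively less RNA of replication genes and of macrophage markers. In the authors' deposited table, 676 of 9326 genes were called, 442 higher and 234 lower in 16N-plus cells. Tubb1, the platelet-specific beta tubulin, was higher by a log2 fold change of 2.26 (SE 0.24) in the authors' deposited table, the integrin Itga6 by 2.05 (SE 0.20) and the serotonin transporter Slc6a4 by 2.07 (SE 0.23). Of 19 surface receptor genes 13 were higher and 0 lower, 15 and 1 adjusted over the list alone, with a median of 1.02 (cameraPR adjusted p = 1.1e-29). Of 29 proplatelet and cytoskeleton genes 16 were higher and 0 lower, 20 and 0 adjusted over the list alone (cameraPR adjusted p = 3.4e-25). Alpha granule genes were higher in 9 of 20 cases, with Ppbp at 1.83 (SE 0.27) in the authors' deposited table, and 13 were higher and 1 lower adjusted over the list alone. All 7 mitochondrially encoded genes were higher, 7 adjusted over the list alone, with mt-Cytb at 2.82 (SE 0.22) and mt-Co1 at 1.89 (SE 0.13) in the authors' deposited table. Of 29 mitosis genes 5 were lower and 0 higher, 10 and 0 adjusted over the list alone, and Mki67, a proliferation marker, was at -1.15 (SE 0.22) in the authors' deposited table. Of 28 DNA replication genes 6 were lower, 12 adjusted over the list alone, with Mcm5, a subunit of the replicative helicase, at -1.33 (SE 0.28) in the authors' deposited table.

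Markers of other cells moved beside these groups. A change within megakaryocytes was therefore not separated from a change in the share of other cells between the gates. Of 19 monocyte and macrophage markers 10 were lower in control 16N-plus cells and 0 higher, 11 and 0 adjusted over the list alone (median -0.87; cameraPR adjusted p = 5.85e-10), among them Vcam1 at -1.95 (SE 0.31) and C1qa at -1.43 (SE 0.27) in the authors' deposited table. Of 18 neutrophil markers 7 were lower, 8 adjusted over the list alone, with Mpo at -1.19 (SE 0.30) in the authors' deposited table. The median log2 fold change over all genes was -0.11; after centring on it, 574 genes were higher and 130 lower, against 442 and 234 as deposited.

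Knockout megakaryocytes of 16N-plus also carried more RNA of platelet genes than 8N cells, with 309 genes called in the authors' deposited table, 196 higher and 113 lower in 16N-plus cells. Ppbp was higher by 1.87 (SE 0.26) and Itga6 by 1.27 (SE 0.21) in the authors' deposited table, while Tubb1 was higher by 1.52 (SE 0.24). Surface receptors were higher for 11 of 19 genes, 15 adjusted over the list alone, with a median of 0.71. Of 29 mitosis genes 1 was lower, 1 adjusted over the list alone, and the list did not pass (median -0.13; cameraPR adjusted p = 0.19). Of 28 DNA replication genes 1 was lower and 1 higher, 7 and 1 adjusted over the list alone, and the list passed lower (median -0.32; cameraPR adjusted p = 0.00032). All 7 mitochondrially encoded genes were higher, 7 adjusted over the list alone, with a median of 1.59. Of 83 cytosolic ribosomal protein genes 19 were lower and 0 higher, 42 and 0 adjusted over the list alone (median -0.51; cameraPR adjusted p = 1.2e-21), with Rpl22 at -1.34 (SE 0.20) in the authors' deposited table. Macrophage markers were lower for 7 of 19 genes and higher for 1, 10 and 2 adjusted over the list alone, and immunoglobulin transcripts were higher, with Igkc at 1.84 (SE 0.23) and Ighm at 1.48 (SE 0.27) in the authors' deposited table. The control and knockout steps shared 126 genes called higher in both, where independent lists would share 9.29, and 34 called lower in both, against 2.84. The largest one-sided Fisher exact p of those was 5.2e-28, and these comparisons share no libraries.

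**Figure D1:**
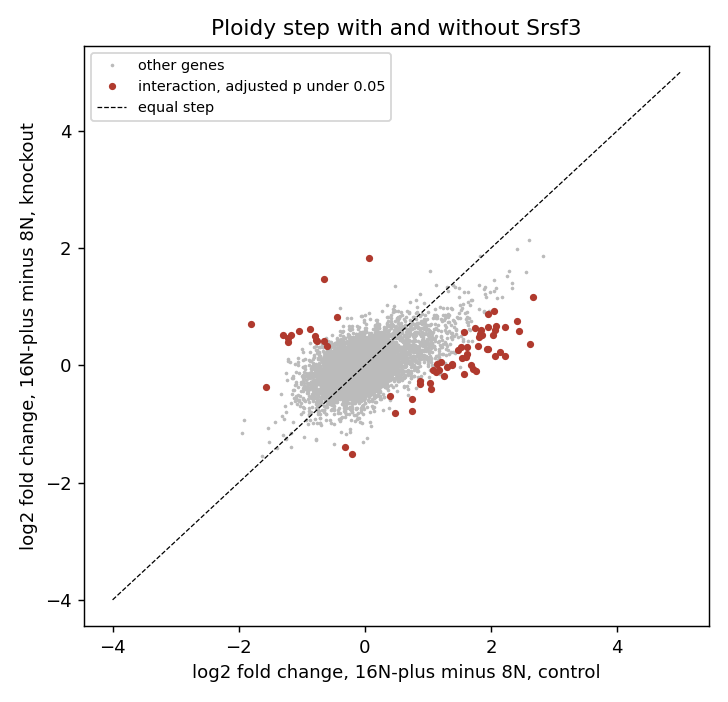
Log2 fold change between 16N-plus and 8N cells in knockout (vertical axis) against control (horizontal axis) for each of the 9326 genes, in the inferred direction, with the 68 genes called in the approximate interaction test in red and a dashed line at equal steps. Of the red points 52 lie below the dashed line.

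In 8N cells the knockout had lower RNA of platelet genes and higher RNA of ribosomal protein genes. The authors' deposited table called 134 of 9326 genes, 28 higher and 106 lower in the knockout. Tubb1 (ENSMUSG00000016255, chromosome 2, 174450695 to 174457882) was at -2.58 (SE 0.24; edgeR adjusted p = 1.7e-19) in the authors' deposited table, the matrix protein gene Thbs1 at -1.77 (SE 0.19) and the lipoxygenase gene Alox12 at -2.11 (SE 0.25). Alpha granule genes were lower for 7 of 20 and higher for 0, 10 and 0 adjusted over the list alone (median -0.49; cameraPR adjusted p = 1.3e-20). Surface receptors were lower for 5 of 19, 8 adjusted over the list alone, and cytoskeleton genes for 7 of 29, 9 adjusted over the list alone. Canonical genes that did not pass were Pf4 at -0.20 (SE 0.26), Gp9 at -0.25 (SE 0.18) and Itga2b at -0.28 (SE 0.08; edgeR adjusted p = 0.057) in the authors' deposited table. Ribosomal protein genes were higher for 21 of 83 and lower for 0, 39 and 0 adjusted over the list alone (median 0.52; cameraPR adjusted p = 1.7e-41), with Rps15a at 1.07 (SE 0.19) and Rps25 at 1.16 (SE 0.22) in the authors' deposited table; ribosomal protein genes have many processed pseudogenes, which can share their reads. Mitochondrially encoded genes moved beside them, with 1 of 7 called higher, 4 adjusted over the list alone (median 0.52; cameraPR adjusted p = 6.0e-06). Nuclear oxidative phosphorylation genes passed as a list (median 0.26; cameraPR adjusted p = 3.4e-11), with 0 of 71 called by the authors' edgeR test, 5 higher adjusted over the list alone and 20 at an unadjusted p under 0.05. Leukocyte markers differed in the same libraries: Lyz1 was at -1.81 (SE 0.22), Igkc at -1.66 (SE 0.23) and Prg2 at -1.32 (SE 0.18), while the T cell factor Tcf7 was at 1.12 (SE 0.19), in the authors' deposited table.

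In 16N-plus cells 327 genes were called in the authors' deposited table, 36 higher and 291 lower in the knockout. Tubb1 was at -3.32 (SE 0.26; edgeR adjusted p = 1.6e-27) in the authors' deposited table, Slc6a4 at -2.91 (SE 0.25), the metalloproteinase gene Mmp19 at -3.01 (SE 0.24) and Tubb2a at -2.93 (SE 0.30). Surface receptors were lower for 9 of 19 genes and higher for 0, 16 and 0 adjusted over the list alone (median -0.72; cameraPR adjusted p = 1.5e-23), with Itgb3, a subunit of the fibrinogen receptor, at -1.21 (SE 0.14) in the authors' deposited table. Alpha granule genes were lower for 8 of 20, 11 adjusted over the list alone, with Vwf at -0.97 (SE 0.12) in the authors' deposited table. Cytoskeleton genes were lower for 11 of 29, 15 adjusted over the list alone, and platelet signalling genes for 7 of 32, 10 adjusted over the list alone, with P2ry12, an ADP receptor, at -1.71 (SE 0.33) in the authors' deposited table. Megakaryocyte transcription factor genes were lower for 3 of 21 and higher for 0, 5 and 0 adjusted over the list alone (median -0.10; cameraPR adjusted p = 0.016). Called or not, 10 members were above 0 and 11 below. Among the called genes were Gata2, at -1.44 (SE 0.25), and Nfe2, at -0.96 (SE 0.29), in the authors' deposited table. Pf4 was at -0.39 (SE 0.28) without passing in the authors' deposited table. Of 29 mitosis genes 1 was higher, 4 adjusted over the list alone (median 0.42), and the neutrophil markers Lcn2, at 1.28 (SE 0.31), and Mmp9, at 1.09 (SE 0.30), were higher in the authors' deposited table. The list of cytosolic ribosomal proteins passed higher at the preset correlation of 0.01 (median 0.24; cameraPR adjusted p = 0.0034) but not at 0.05 (cameraPR adjusted p = 0.135), with 0 of 83 called by the authors' edgeR test, 0 adjusted over the list alone and 7 at an unadjusted p under 0.05. Mitochondrially encoded genes had 1 of 7 called lower, 1 adjusted over the list alone (median -0.27; cameraPR adjusted p = 0.0048), with mt-Co1 at -0.63 (SE 0.12) in the authors' deposited table, opposite in direction to the same list in 8N cells.

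**Figure D2:**
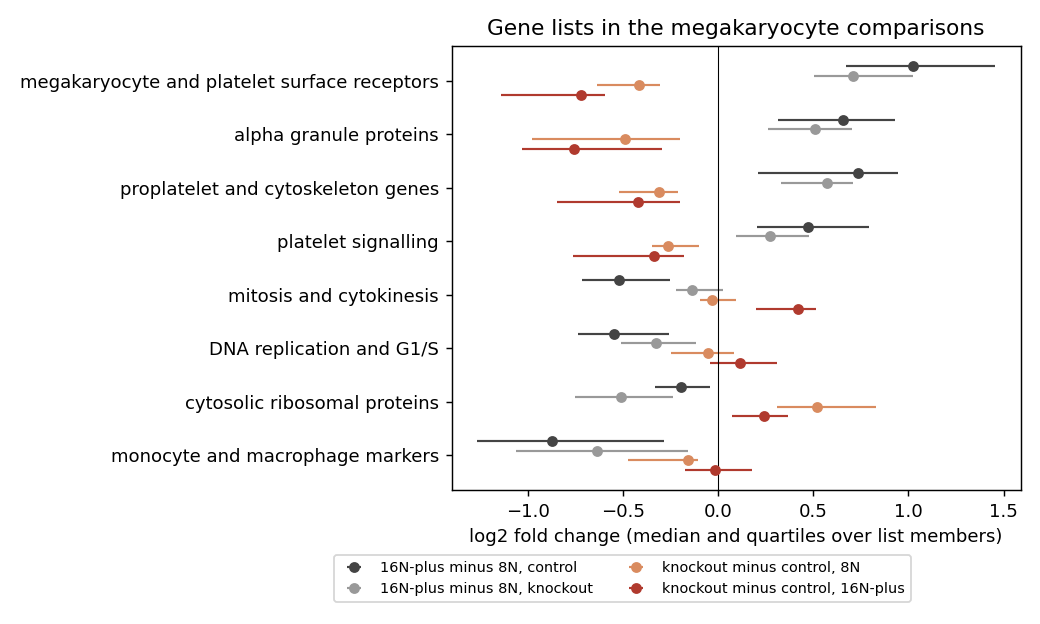
Median log2 fold change (points) and quartiles over members (bars) of 8 gene lists in the 4 megakaryocyte comparisons, in the inferred direction. Surface receptors have medians of 1.02 and 0.71 for ploidy in control and knockout and of -0.42 and -0.72 for genotype in 8N and 16N-plus cells.

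The genotype calls at both ploidies shared 71 genes lower in both, where independent lists would share 3.31 (one-sided Fisher exact p = 8.1e-84). They shared 0 genes higher in both, where 0.108 would be shared. Whether both gates came from the same mice is not given in the sample titles, and mice in common would make these comparisons dependent. In the authors' deposited table that combines ploidies, which equals the mean of both genotype tables, 391 genes were called, 58 higher and 333 lower, against 36 and 468 after centring on the median gene. Of the 442 genes higher with ploidy in controls, 248 were lower in knockout 16N-plus cells, where independent lists would share 13.8. The same control 16N-plus libraries enter both with opposite sign. Simulated groups with no effect gave a correlation across genes of -0.45, against -0.75 observed. It was -0.89 when the shared group held all of the smaller variance. This overlap is therefore not free of the shared libraries. The first simulation called 0 such genes, which cannot decide the question, since almost no gene passes the adjustment where nothing changed. The covariance was -0.12 against -0.029 and -0.058 in these simulations.

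The effect of genotype differed between ploidies for 68 of 9305 genes in the approximate interaction test, 16 with a higher and 52 with a lower knockout effect in 16N-plus cells. Mmp19 differed by -1.91 (SE 0.28; adjusted p = 2.4e-08 by the normal approximation on the authors' edgeR values), the phosphatidate phosphatase gene Lpin2 by -2.26 (SE 0.38) and Gata2 by -1.45 (SE 0.28). Lyz1 differed by 2.51 (SE 0.31), Ighm by 2.12 (SE 0.40) and Mmp9 by 1.82 (SE 0.36), which are transcripts of myeloid and B cells. Neutrophil markers as a list had a median difference of 0.94, with 3 of 18 called higher and 12 adjusted over the list alone. Surface receptors had a median difference of -0.38 with 0 of 19 called by the same test and 0 adjusted over the list alone, and 5 at an unadjusted p under 0.05 (cameraPR adjusted p = 0.00015). Tubb1, Itgb3 and Thbs1 were not among the genes called, so their effect was not shown to differ between ploidies.

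In platelets the knockout had lower RNA of most surface receptor and alpha granule genes and higher RNA of ribosomal, oxidative phosphorylation and red cell genes. Whether red cell RNA in these libraries raised the ribosomal and oxidative phosphorylation genes was not tested. The authors' deposited table called 6707 of 12611 genes, 3553 higher and 3154 lower. The vesicle fusion gene Stx11 was at -6.27 (SE 0.17), the growth factor gene Pdgfa at -8.41 (SE 0.33), the tetraspanin gene Tspan2 at -8.90 (SE 0.35) and Tubb1 at -5.59 (SE 0.23) in the authors' deposited table. Surface receptors were lower for 14 of 18 tested genes and higher for 1, 14 and 1 adjusted over the list alone (median -1.91; cameraPR adjusted p = 4.6e-07), among them Itga6 at -2.49 (SE 0.14) and Gp9 at -1.60 (SE 0.23) in the authors' deposited table. Alpha granule genes were lower for 12 of 20 and higher for 4, 12 and 4 adjusted over the list alone, with F5, clotting factor V, at -3.57 (SE 0.16) and Pf4 at -1.50 (SE 0.25) in the authors' deposited table. Platelet signalling genes were lower for 18 of 32 and higher for 8, 18 and 8 adjusted over the list alone, with the ADP receptor gene P2ry1 at -7.01 (SE 0.31) in the authors' deposited table. Proplatelet and cytoskeleton genes were lower for 10 of 23 and higher for 5, 12 and 5 adjusted over the list alone, and the list did not pass (median -0.48; cameraPR adjusted p = 0.070). Gp1ba, at -0.27 (SE 0.25), Myh9, at -0.07 (SE 0.14), and Actb, at -0.16 (SE 0.20), did not pass in the authors' deposited table. Oxidative phosphorylation genes were higher for 55 of 66 and lower for 3, 55 and 3 adjusted over the list alone (median 1.97; cameraPR adjusted p = 7.5e-19), with Ndufa6 at 3.15 (SE 0.13) in the authors' deposited table. Ribosomal protein genes were higher for 16 of 20 tested, 17 adjusted over the list alone, some of them ribosomal-like paralogues such as Rpl39l. Red cell markers were higher for 13 of 15 and lower for 0, 13 and 0 adjusted over the list alone (median 4.98; cameraPR adjusted p = 0.0070), with Alas2, the first enzyme of heme synthesis in red cells, at 6.57 (SE 0.96) and Slc4a1 at 6.49 (SE 0.91) in the authors' deposited table. Of 13 neutrophil markers 0 were called by the authors' DESeq2 test and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05 and a median of 0.11.

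Genes lower in knockout 16N-plus megakaryocytes were mostly lower in knockout platelets: 228 were called lower in both among 8163 genes tested in both, where independent lists would share 74.6 (one-sided Fisher exact p = 2.5e-88). In 8N cells 62 were shared, against 24.5. Sharing was weaker among genes called higher in both: 18 for 16N-plus cells, against 11.0 (one-sided Fisher exact p = 0.0089), and 6 for 8N cells, against 3.78 (one-sided Fisher exact p = 0.14). Across genes, which are not independent replicates, fold changes in 16N-plus megakaryocytes and in platelets had a Spearman correlation of 0.30, and 246 of 259 genes called in both had the same sign. The platelet direction was chosen from this relation, so its sign carries no evidence of its own. With the platelet signs alone turned, the genes shared in the same direction would be shared in opposite directions.

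**Figure D3:**
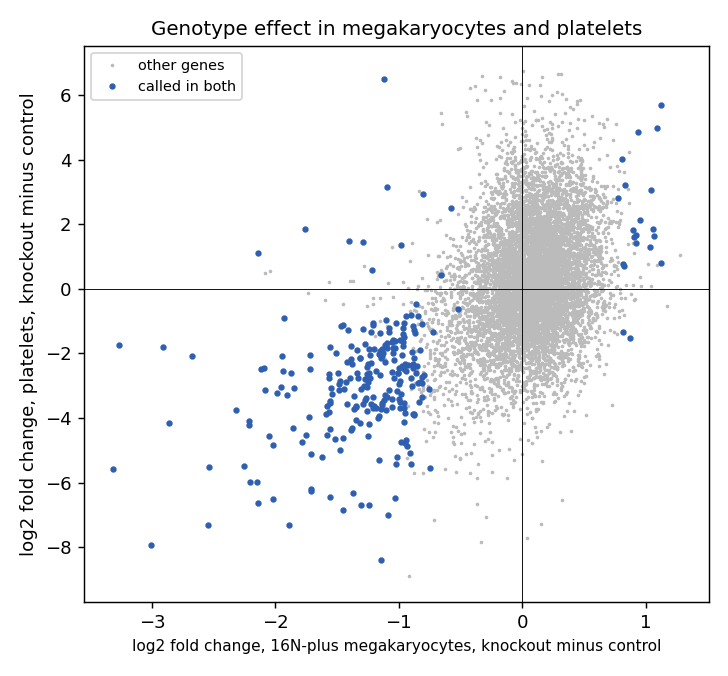
Log2 fold change between knockout and control in platelets (vertical axis) against 16N-plus megakaryocytes (horizontal axis) for each of the 8163 genes tested in both, in the inferred direction, with the 259 genes called in both in blue. Of the blue points 228 lie in the lower left.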

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

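Tests on other blood cells, on library spread, on a common fraction of cells, on the fixed lists and on a lower platelet share were chosen after the result they bear on was seen; those on transcript length, on selection and on the second erythroid list were chosen before. Other splits of the samples could not be counted, since values per library were not used here.

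The knockout effect differed between ploidies, in a test of the difference itself, for genes whose effect was lower in 16N-plus than in 8N cells: Lpin2 by -2.26, Prokr1 by -2.08, Mmp19 by -1.91, Mest by -1.90, Nrip1 by -1.71, Tubb2b by -1.68, Birc2 by -1.67, Tubb2a by -1.65, Neb by -1.57, Atp5e by -1.53, mt-Nd1 by -1.50, Gata2 by -1.45, Slc6a4 by -1.39, Gzma by -1.31, Rps13 by -1.30, Lyl1 by -1.25 and Rps12 by -1.07 on the log2 scale. It was higher for Lyz1 by 2.51, Ighm by 2.12, Mmp9 by 1.82, Igkc by 1.77, Itgam by 1.68, Itln1 by 1.68, Lcn2 by 1.64, Chil3 by 1.61 and Prg2 by 1.19. The same test on lists passed with lower medians for mitochondrially encoded genes (-0.92), surface receptors (-0.38), ribosomal proteins (-0.26), platelet signalling (-0.21), T and NK cell markers (-0.21), oxidative phosphorylation (-0.15), proplatelet and cytoskeleton genes (-0.11) and dense granule genes (-0.0902). It passed with higher medians for neutrophil (0.94), mitosis (0.42), B cell (0.41), eosinophil, basophil and mast cell (0.34), DNA replication (0.26) and monocyte and macrophage lists (0.22). With a preset correlation of 0.05 only 7 of these 14 lists passed: mitochondrially encoded, surface receptor and ribosomal protein genes lower, and neutrophil, mitosis, B cell and eosinophil, basophil and mast cell lists higher. By a Fisher exact test of called members only 2 passed, the neutrophil and B cell lists.

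Ribosomal protein genes were higher in 8N knockout cells, with a median log2 fold change of 0.52, beside mitochondrially encoded genes at 0.52 and nuclear oxidative phosphorylation genes at 0.26. A bias towards short transcripts was tested on 249 other coding genes matched on transcript length and expression. Their median was 0.0328 (interval over genes 0.0022 to 0.080), far below the size such a bias would need at these lengths. Lengths were those of the longest annotated transcript, with a median of 1129 bases in the matched genes against 914 in the ribosomal protein genes. A bias confined to shorter transcripts was therefore not excluded. RNA of other blood cells in the sort cannot be told apart: 7 of the 8 other-cell lists had medians below 0, but the T and NK cell list stood at 0.29 with an interval of 0.08 to 1.22 over 6 genes. The CD41 sort selects against cells without CD41. An effect of genotype stays open as a hypothesis.

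The ploidy step was smaller in knockout cells for the genes called in controls, and part of this may come from choosing genes by their control step. Among the 309 genes chosen by their knockout step instead, the control step was the smaller, with a ratio of control to knockout medians of 0.90 (0.82 to 1.00). Selection alone would not give the difference over the 100 members of 4 lists fixed in advance, called or not, where the knockout step was smaller by a median of -0.22 (-0.31 to -0.12). Noise in the knockout step that is independent between genes would not lower the slope of the knockout step on the control step, which was 0.574 (0.545 to 0.602) across genes after correction for control noise; spread shared by many genes was not tested. A common fraction of 8N-like cells in the knockout 16N-plus gate remains possible for those 4 lists: with 0.43 of the RNA 8N-like, the residuals had a standardized SD of 1.05, inside the simulated 0.86 to 1.15. It would not give the ribosomal protein step, larger in knockout (median -0.51) than in control (-0.19), or neutrophil markers at 0.28 in knockout against -0.50 in control, and an effect of genotype stays open.

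Red cell genes were higher in knockout platelets. The medians of the erythroid list and 60 leukocyte markers differed by 5.48 (4.13 to 6.82), with a pooled leukocyte median of -0.51. This gap cannot decide whether a lower platelet share raised all other blood cells alike. The deposited platelet fold changes appear moderated at low signal, and the leukocyte markers were not matched to the erythroid genes on expression. Leukocyte markers of low signal could therefore lie near no change whatever their true change. Red cell RNA carried over with the platelets is consistent with a second erythroid list, 3.97 (2.69 to 5.32) above expression-matched genes, with 18 of 22 tested genes higher and 1 lower. In knockout megakaryocytes the first erythroid list was not higher, with medians of -0.26 in 8N and -0.15 in 16N-plus cells. Whether the red cell RNA in platelet libraries came from co-purified red cells or from the platelets themselves was not tested.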

How the results depend on the processing

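No paired analysis was possible because the files used here hold the authors' comparisons and no values per library; for the same reason TMM or DESeq2 size factors, the DESeq2 Wald test, limma-voom, count and value filters, pseudocounts, fits of 2 groups only, leave-one-out, a replicate block and an estimated correlation were not run. Centring and the other SE estimates were added after the data were seen. No result changed sign in the settings run. At an adjusted p under 0.01, fewer genes were called by construction: 405 for the control ploidy step, 176 for the knockout step, 81 for genotype in 8N cells, 259 for both ploidies and 43 for the interaction. With an absolute log2 fold change of at least 1 these were 321, 71, 42 and 83 for the first 4. Genes lower with genotype at both ploidies fell from 71 to 45 and 24 under those settings, shared ploidy calls from 126 to 80 and 36 (higher) and from 34 to 17 and 10 (lower), 8N calls shared with platelets from 62 to 40 and 19 (lower) and from 6 to 2 and 0 (higher), and 16N-plus calls shared with platelets from 18 to 7 and 6 (higher). Control ploidy calls lower that were higher in knockout 16N-plus cells fell from 16 to 2 and 3. With a Fisher exact test of called members in place of cameraPR, fewer lists passed: 9 against 16 for the knockout step, 7 against 17 for genotype in 8N cells, 4 against 12 in 16N-plus cells, 5 against 16 for both ploidies and 2 against 14 for the interaction. With a preset correlation of 0.05, 8 lists passed for both ploidies and 7 for the interaction, and 8 of 12 in 16N-plus cells (ribosomal protein, transcription factor, erythroid and p53 lists lost their call), 13 of 16 for the knockout step, 15 of 17 in 8N cells, 11 of 12 for the control step and 8 of 9 in platelets; the cause of these list changes was not tested. Srsf3 was not called in any setting. The interaction called 68 genes with SEs from the ploidy tables, 60 of them among the 68 main calls, and 63 with the median of 3 SE estimates. Depth per library is unknown and sets a limit that could not be examined.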

Other observations

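Other gene groups of the platelet comparison were not described above. Of 20 unfolded protein and stress response genes 13 were higher in knockout platelets and 3 lower, 13 and 3 adjusted over the list alone (median 2.23; cameraPR adjusted p = 0.0040), with the chaperone gene Calr at 4.04 (SE 0.19) and Dnajb9 at -3.59 (SE 0.21) in the authors' deposited table. Of 15 stem and progenitor markers 8 were lower and 0 higher, 8 and 0 adjusted over the list alone, with Angpt1 at -3.77 (SE 0.18) in the authors' deposited table. Spliceosome and hnRNP genes were higher for 18 of 31 and lower for 4, 18 and 5 adjusted over the list alone (median 0.79; cameraPR adjusted p = 0.0063). Of 10 SR splicing factors other than Srsf3, 2 were higher and 1 lower, 1 and 1 adjusted over the list alone, and the list did not pass (median 0.03, mean -0.28; cameraPR adjusted p = 0.59). Among them Srsf2 was at -4.39 (SE 0.19) and Srsf9 at 1.57 (SE 0.32) in the authors' deposited table. Of 23 interferon response genes 12 were higher and 2 lower, 12 and 2 adjusted over the list alone, and the list did not pass (cameraPR adjusted p = 0.40).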
